A study of Homo sapiens with 2 samples.

How the data were processed

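ChIP-seq was performed on untreated t-HESC cells with an antibody against EGR1, and an input library was made from the same line. Per the labels' protocols, nuclei were sonicated, adapters were ligated, fragments were size-selected on an agarose gel and amplified by PCR, and the libraries were sequenced on an Illumina NextSeq instrument. Per the submitters' processing notes, BWA, MACS and MACS2 2.1.0 were used with build GRCh37.p2. Their order, options, filters and significance threshold are not given in the sources used here. How duplicate reads were treated is likewise not given, and it bears on the scores because the libraries were amplified by PCR.

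The deposited data analysed were a list of 7709 intervals and a list of their summits, both from the ChIP library. The interval and summit positions (unit: other) were used as deposited by the authors. Every summit lay inside the interval in the same place of the list. The intervals on chromosome 1 reached position 249200710. The authors deposited 1 score per summit, a whole number from 11 to 336, and neither its unit nor any scaling is given in the sources used here. It was used only to rank, filter and describe intervals within this list. The strength of each interval against the input was not analysed here. Peaks came from 1 ChIP library, so no overlap between replicates could be taken. Read counts were not used here, so depth is unknown.

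Interval starts were treated as BED starts, and printed starts are 1-based. Chromosome length was taken as the distance between the first and the last interval. Density is the number of intervals per Mb of that length, with an exact Poisson 95% interval, and ratios of densities have exact conditional binomial 95% intervals. Shares have exact Clopper-Pearson 95% intervals. Regional gathering was measured as the variance over the mean of summit counts in 1 Mb bins, taken within chromosomes. Intervals whose edges lay within 1000 bp were joined into 1 site. Both measures, and the share of intervals in the densest 5% of bins, were set beside 1000 random placements of the same intervals in their own chromosome's span, which includes unsequenced gaps such as centromeres. Close pairs were also counted after moving each interval within its own 1 Mb bin or its own 100 kb. Correlations across chromosomes used 100000 permutations, two-sided, and that of width with score has the SD of 500 bootstrap resamples of intervals. Stricter sets were the 3930 intervals with a score at or above the median of 26 and the 788 at or above the 90th percentile of 57. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

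The placement measures were tested on simulated data of 7709 intervals. In 20 sets placed at random, the variance over the mean averaged 1.01 and none of the sets was above all of its 100 random placements, for either measure. With 500 close pairs planted, the excess of close pairs averaged 498 and was found in 20 of 20 sets. With a planted regional excess, 20 of 20 sets were above all random placements in variance over mean, and 3 of 20 were so in close pairs although none were planted, with a mean excess of 9.67 pairs. Close pairs were also set beside placements that keep the regional density.

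Before the data were examined, a plan was fixed to place intervals on promoters, to name genes by the score of their promoter interval and by fixed gene lists, and to count the EGR1 motif at summits. These steps need a genome and gene models on GRCh37. The reference table at hand is on GRCh38.p14, and positions were not converted between builds. Gene assignment, gene list and motif results are therefore not reported, and the plan's fallback for this case was followed: number, width, score, spacing and chromosome share of intervals. The intervals named are the 10 with the highest scores, the widest one, the densest regions and the sites with 5 intervals. Alternatives varied the score limit, the joining of neighbours, the bin size and the distance that counts as close.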

Results

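Genomic intervals enriched with an antibody against EGR1 were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in untreated t-HESC cells. EGR1 is a zinc-finger transcription factor encoded by an immediate early gene, and it binds GC-rich DNA. The t-HESC line is an immortalised line of human endometrial stromal cells, the connective tissue cells of the uterine lining. The series held 1 EGR1 ChIP library and 1 input library of sonicated chromatin DNA, each without a replicate. The question addressed was where in the genome of these cells EGR1 was bound. Each value below therefore describes 1 library, and no test of variation between cultures was possible. Read totals of the 2 libraries are not given in the sources used here, so the depth is unknown. The intervals printed below, exact Clopper-Pearson for shares and exact Poisson for counts, are at the 95% level and cover counting error only. They treat intervals as independent, although neighbouring intervals lay close together, so they are too narrow. Neither the EGR1 motif nor the strength of enrichment over the input was analysed here. The called intervals are thus not shown to be sites of EGR1 binding.

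EGR1 enrichment was called at 7709 intervals on 23 chromosomes, and the intervals were short. Their median width was 343 bp (quartiles 255 and 490 bp, range 207 to 2242 bp). Together they covered 3160318 bp, or 0.109% of the sequence between the first and the last interval of each chromosome. The authors gave each interval 1 summit with a whole-number score, whose unit is not given in the sources used here. The median score was 26 (quartiles 20 and 37), the 90th percentile was 57, and the range was 11 to 336. A score over 100 was reached by 164 intervals, or 2.13% of all intervals (95% interval 1.82 to 2.47%). The summit lay near the middle of its interval, at a median of 45.2% of the width from the lower coordinate.

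The EGR1 interval with the highest score lay on chromosome 17, at positions 49230557 to 49231499 (GRCh37). Its summit score was 336, against a median of 26 for all intervals, and it was 943 bp wide. The next interval, on chromosome 16 at positions 31191009 to 31191892, had a score of 241. It was followed by one on chromosome 1 at positions 10458312 to 10459310, with a score of 227. An interval on chromosome 20 at positions 55043134 to 55043660 had a score of 226. Chromosome 19 held the next pair, at positions 48281168 to 48282377 with a score of 215 and at positions 36869462 to 36870232 with a score of 214. A score of 212 was shared by an interval on chromosome 3, at positions 42641752 to 42642336, and one on chromosome 17, at positions 37212951 to 37213771. The last 2 of the 10 highest-scored intervals lay on chromosome 8 at positions 124408438 to 124409158, with a score of 196, and on chromosome 11 at positions 77705492 to 77706224, with a score of 194. These 10 intervals were 527 to 1210 bp wide, all wider than the median interval, and they lay on 8 chromosomes. They were picked by score after the values were seen. The genes at these positions were not analysed here.

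Higher-scored EGR1 intervals were wider. In the 771 intervals with the lowest scores (11 to 17) the median width was 246 bp, with quartiles of 212 and 304 bp. In the 770 with the highest scores (57 to 336) it was 663.5 bp, with quartiles of 512 and 855 bp. Across intervals, which are not independent replicates, Spearman's rho between width and score was 0.639 (bootstrap SD 0.007). Width and score come from the same library and the same stretch of sequence, so how intervals were called may contribute to this relation. That was not tested. The widest interval, 2242 bp on chromosome 12 at positions 57480369 to 57482610, had a score of 102. A width of exactly 207 bp, the smallest, was shared by 369 intervals (4.79%, 95% interval 4.32 to 5.29%), and 152 of these were among the 771 with the lowest scores.

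**Figure D1:**
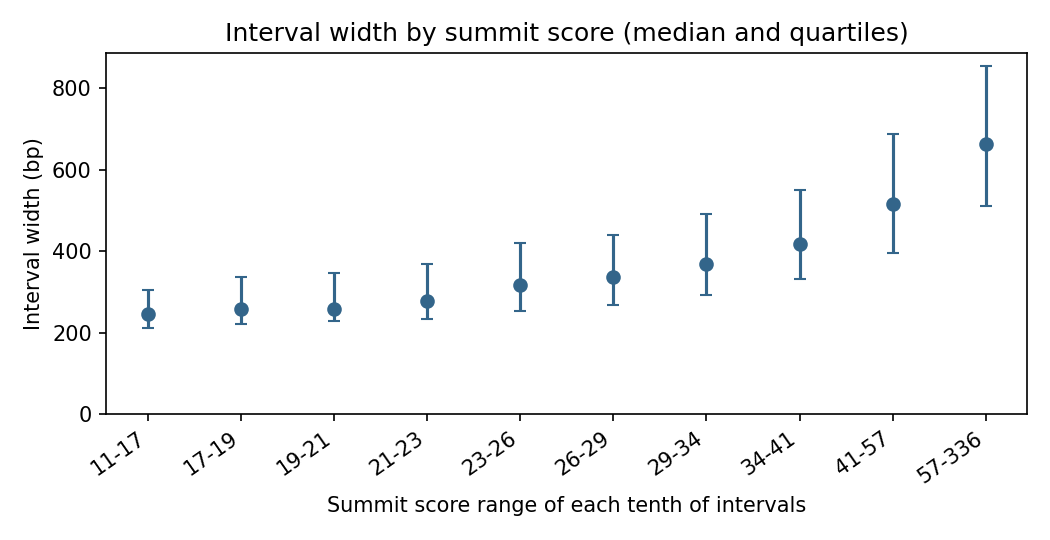
Interval width in bp (vertical axis) against summit score, for 10 equal parts of the 7709 intervals ranked by score (horizontal axis, with the score range of each part). Points are medians and bars run from the lower to the upper quartile, and the median rises from 246 bp in the lowest part to 663.5 bp in the highest.

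EGR1 intervals were concentrated on chromosome 19 and on chromosomes 17, 22 and 16, and were sparse on chromosomes X, 4 and 18. Chromosome 19, the most gene-dense human chromosome, held 674 intervals, 8.74% of the total (95% interval 8.12 to 9.40%). Its density was 11.5 intervals per Mb (95% interval 10.6 to 12.4), where the length is that between the first and the last interval of a chromosome. Chromosome 17 had 6.98 intervals per Mb (6.41 to 7.58), chromosome 22 had 5.85 (5.06 to 6.73) and chromosome 16 had 4.06 (3.65 to 4.49). These 4 chromosomes held 23.3% of the intervals on 9.02% of the summed length. Over all chromosomes the density was 2.65 intervals per Mb. Chromosome X had the lowest density, 0.911 per Mb (0.764 to 1.08), from 134 intervals. Chromosome 4 had 1.42 per Mb (1.26 to 1.60), and chromosome 18, a gene-poor chromosome, had 1.48 per Mb (1.22 to 1.78). Gene density, copy number and mappability were not set beside these densities. The cause of the differences between chromosomes was therefore not tested.

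The density on chromosome 19 was 12.6 times that on chromosome X (95% interval 10.4 to 15.3) and 7.74 times that on chromosome 18 (6.34 to 9.52). Chromosomes 19 and X are the densest and the sparsest of the 23, and the interval of their ratio does not allow for that choice. The small chromosomes 22 and 21 differed by a factor of 1.98 (1.54 to 2.56), with 195 and 95 intervals. The ratio of chromosome 19 to chromosome X was also taken by score. It was 9.49 (95% interval 7.36 to 12.4) in the 3779 intervals with a score below 26 and 16.8 (12.7 to 22.6) in the 3930 with a score of 26 or more. Among the 788 intervals with a score of 57 or more it was 19.5 (9.69 to 44.3), from 70 intervals on chromosome 19 and 9 on chromosome X. Chromosome 19 held 8.88% of these 788 intervals (6.99 to 11.1%), close to its 8.74% of all intervals. Chromosome X held 1.14% (0.524 to 2.16%), against 1.74% of all intervals, so the last ratio rests on few intervals there. Across the chromosomes, no relation between score and density passed the test. Median scores lay between 23.5 on chromosome X and 27 on chromosomes 8, 16, 18, 19 and 21. Over the 23 chromosomes, density and median score gave a Pearson r of 0.23 (permutation p = 0.288, Benjamini-Hochberg adjusted 0.432) and a Spearman rho of 0.03 (permutation p = 0.885, adjusted 0.885), both two-sided. Density and the 95th percentile of score gave r = 0.06 (permutation p = 0.779, adjusted 0.779) and rho = 0.04 (permutation p = 0.851, adjusted 0.885). Density and median width gave r = 0.36 (permutation p = 0.0923, adjusted 0.277) and rho = 0.38 (permutation p = 0.0722, adjusted 0.217). These 3 relations were the whole family for each coefficient, and Pearson and Spearman p-values were adjusted separately. Without chromosomes 19 and 17, the farthest from the median density, r was 0.13 for the median score, 0.29 for the 95th percentile and 0.31 for the width.

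**Figure D2:**
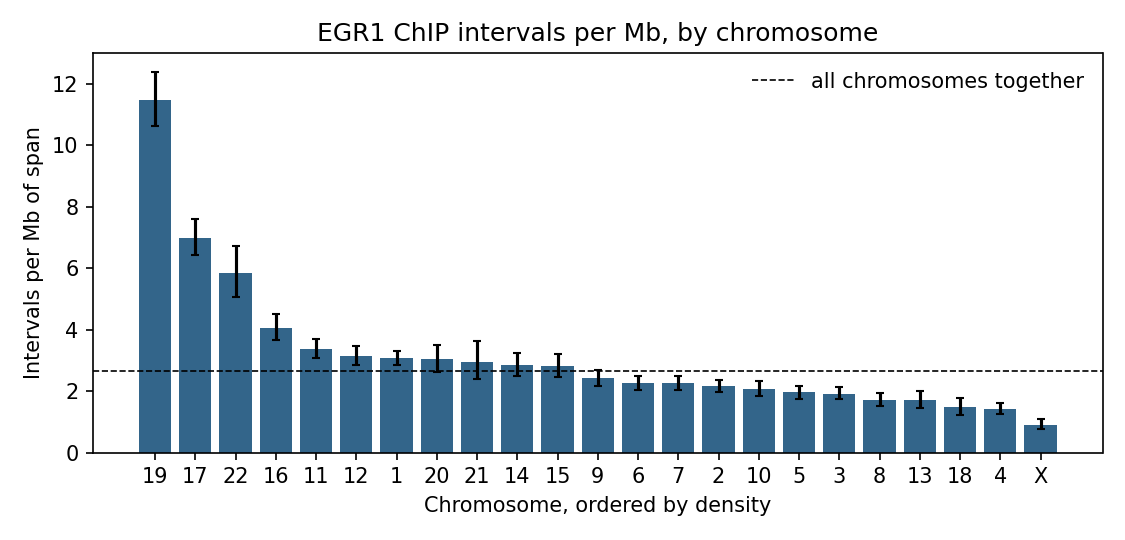
Density of EGR1 ChIP intervals (vertical axis, intervals per Mb between the first and last interval) on each of the 23 chromosomes (horizontal axis, from the densest to the sparsest). Bars are the density of the 1 ChIP library, error bars are exact Poisson 95% intervals, and the dashed line is the 2.65 per Mb of all chromosomes together, with chromosome 19 at 11.5 and chromosome X at 0.911.

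Within chromosomes, EGR1 intervals were spread unevenly. The genome was divided into 2932 bins of 1 Mb. The densest 5% of the bins held 30.8% of the intervals. When the intervals were placed at random on their own chromosomes, this share had a mean of 18.4% and was at most 18.9%. No interval lay in 1128 bins (38.5%). These include bins in unsequenced gaps, and their number was not set beside random placements. The densest bin, on chromosome 19 at positions 1000001 to 2000000, held 46 intervals (95% interval 33.7 to 61.4), against a mean of 2.63 per bin. A bin on chromosome 11 at positions 65000001 to 66000000 held 44 (32 to 59.1). Chromosome 19 at positions 18000001 to 19000000 followed with 36 (25.2 to 49.8) and chromosome 17 at positions 7000001 to 8000000 with 34 (23.5 to 47.5). Of the 26 bins with at least 20 intervals, 9 lay on chromosome 19, 5 on chromosome 17 and 4 on chromosome 11. The 3 Mb of chromosome 11 from 64000001 to 67000000 held 101 intervals, or 22.3% of that chromosome's intervals on 2.24% of its length. On chromosome 19, the 13 Mb from 20000001 to 33000000 held 3 intervals (0.619 to 8.77), and the remainder of the chromosome had 14.7 per Mb. That stretch takes in the centromere and its unsequenced gap, where no read can map. Its 3 intervals lay in the bins that start at 20000001, 23000001 and 30000001, so part of the stretch could be mapped. How much of the stretch is gap was not analysed. These regions were picked after their values were seen.

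The variance of the counts per bin, taken within chromosomes, was 4.76 times the mean. In 1000 random placements of the same intervals within their own chromosomes this ratio averaged 1.02 and reached 1.11 at most. In the 788 intervals with a score of 57 or more the ratio was 1.42, above the highest random placement of 1.09. Equally many intervals drawn at random from the full set gave 1.37 on average (range 1.21 to 1.57), and the observed value lay within that range. The median score was 25 in the 465 intervals that were alone in their bin (quartiles 20 and 37) and 26 in the 683 intervals of bins with 20 or more (quartiles 21 and 36).

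**Figure D3:**
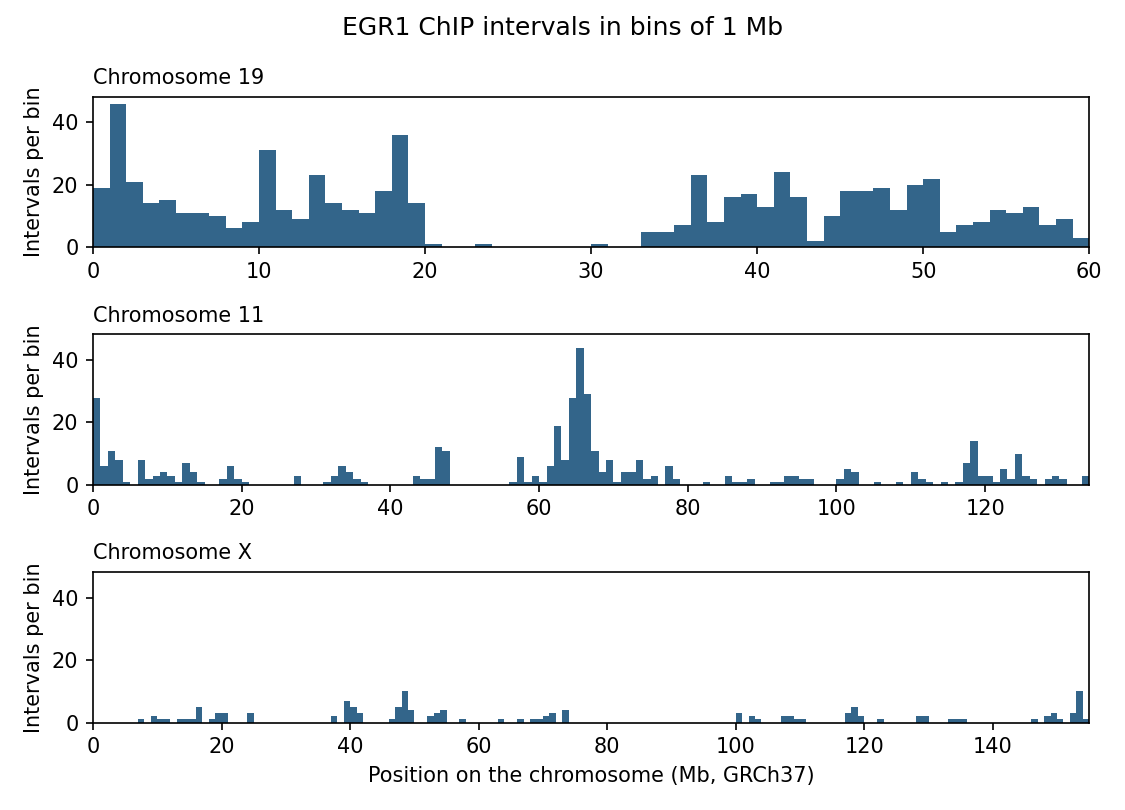
Number of EGR1 ChIP intervals per 1 Mb bin (vertical axis) along chromosomes 19, 11 and X (horizontal axis, position in Mb, GRCh37) in the 1 ChIP library. The tallest bins hold 46 intervals on chromosome 19 and 44 on chromosome 11. Chromosome 19 holds 3 intervals from 20 to 33 Mb. Part of that stretch is the unsequenced gap of the centromere, where no read can map, and the size of that part was not analysed.

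At short range, EGR1 intervals lay close to one another far more often than random placement gave. Of the adjacent pairs, 1136 were separated by at most 1 kb, 28.2 times the mean of 40.3 in random placements (highest of 1000 placements, 61). When each interval was moved at random only within its own 1 Mb bin, the mean was 89.9 pairs and the highest 123. Within its own 100 kb, the mean was 157 and the highest 197. Joined at 1 kb, the intervals formed 6573 separate sites. Of these, 5607 were single intervals, and 823 sites had 2 intervals, 120 had 3, 19 had 4 and 4 had 5. The 966 sites with several intervals spanned a median of 1155 bp (quartiles 903 and 1499 bp) and took in 27.3% of all intervals (95% interval 26.3 to 28.3%). Cutting of 1 enriched stretch into several intervals by the peak caller was not tested for the close pairs. The sites with several intervals are therefore not shown to hold separate binding events.

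The sites with 5 intervals lay on chromosomes 7, 17 and 19, and none of their members had a score above 57. The site on chromosome 7, at positions 100807890 to 100810426, had scores of 16 to 29. On chromosome 17, one site at positions 1388229 to 1392012 had scores of 23 to 43 and another at positions 77770760 to 77775083 had scores of 15 to 25. The site on chromosome 19, at positions 18525987 to 18529930, had scores of 18 to 57. Intervals that stood alone had a median score of 26 (quartiles 20 and 38), and those in sites of several had 25 (quartiles 20 and 35). A score over 100 was found in 2.32% of the single intervals (95% interval 1.94 to 2.75%) and in 1.62% of the grouped ones (1.12 to 2.25%). The share of intervals that lay in sites of several was 28.3% among the 771 with the lowest scores and 21.7% among the 770 with the highest. Among the 788 intervals with a score of 57 or more there were 4 close pairs, against a mean of 12.6 (range 3 to 26) in random draws of as many intervals.

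**Figure D4:**
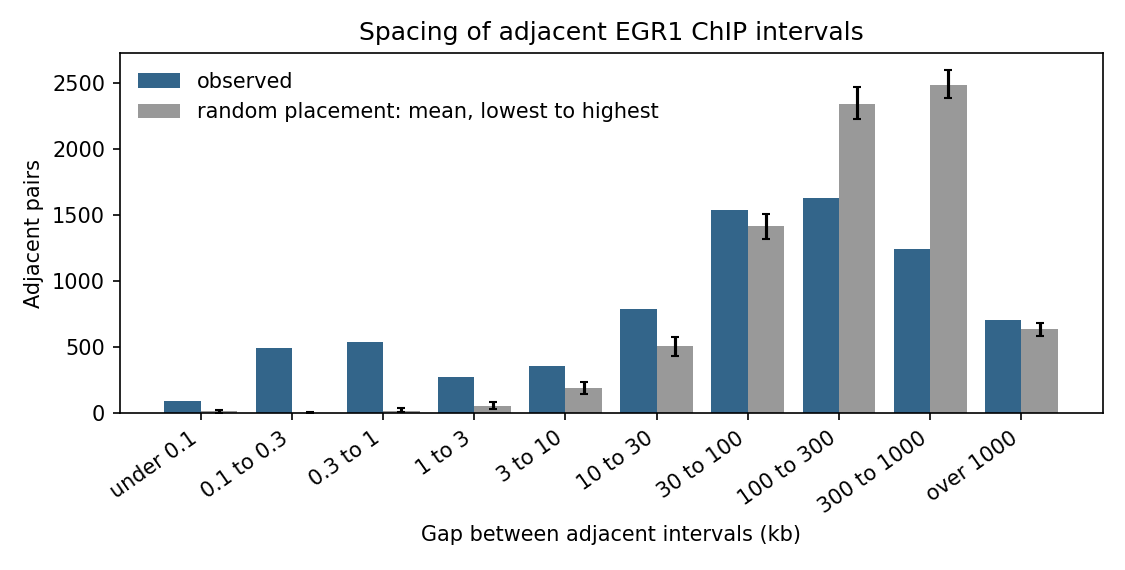
Number of adjacent interval pairs (vertical axis) by the gap between them (horizontal axis, kb), in the ChIP library and in 1000 random placements of the same intervals on their own chromosomes; overlapping pairs, which occur only in the random placements, are in the first class. Bars for random placements are means with lines from the lowest to the highest, and 544 observed gaps lay between 0.3 and 1 kb against a random mean of 19.98.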

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

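The alternatives were chosen after seeing the data, except those for the number of intervals. That number was 3930 at a score of 26 or more and 788 at a score of 57 or more, by construction, and 6573 after joining neighbours within 1000 bp. The 1136 close pairs fell to 276 at a score of 26 or more, still above the highest of 1000 random placements (30). Equally many intervals drawn at random from the full set gave 304 on average (259 to 352). The 276 lay within that range but below its mean, so having fewer intervals gives a drop of about this size. These draws do not decide whether pairing also depends on score. Intervals with a score of 57 or more held 4 close pairs, against 3 to 26 in random draws of that size. The density of chromosome 19 over chromosome X was 9.49 at a score below 26 (95% interval 7.36 to 12.4) and 16.8 at a score of 26 or more (95% interval 12.7 to 22.6). At 57 or more it was 19.5 (9.69 to 44.3), from only 9 intervals on chromosome X. The cause of these differences was not tested. Spearman's rho between width and score was 0.61 without the intervals of the smallest width and 0.533 at a score of 26 or more, where the range of scores is narrower by construction. The variance over mean stayed above the highest random placement under all 5 alternatives run (1.42 to 6.74), and so did the close pairs under the 3 run. The lack of replicates and of read depth limits all values to this library. Alternatives listed for promoter share, genes with a promoter interval, motif share and gene lists were not run, because they need gene models and sequence on GRCh37.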

Other observations

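Chromosome 11, which holds a dense block of EGR1 intervals, had a slightly low median score. It was 24 over 452 intervals, and 1.71% of 10000 random draws of 452 intervals from all chromosomes had a median as low. Its quartiles of 20 and 37 equalled those of all intervals, and its 95th percentile of 72.5 was close to the 72.4 of chromosome 19. The block from 64 to 67 Mb and the 351 intervals elsewhere on the chromosome both had a median score of 24, so the low median was not confined to the block. Chromosome X, with 134 intervals, had a median of 23.5, and 2.37% of random draws were as low. On chromosome 19, the median was 27 and 5.67% of random draws were as high. All 23 chromosomes were compared in this way and the percentages are not adjusted for that number.

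All tests in this section were chosen after the result was seen. The uneven density of intervals within chromosomes was set against technical explanations. Bins where no read can be mapped do not account for the whole pattern: with every empty bin set aside, the variance over mean within chromosomes was 3.414 against at most 0.824 when intervals were dealt at random to the remaining bins. Cutting of 1 site into intervals at most 1000 bp apart does not either, since the ratio after joining such neighbours was 3.803 against at most 1.107. Cutting with wider gaps was not tested. Copy number differences, and partial mappability within bins, remain open, as does gene density, which is the candidate a biologist would test first; the design has 1 group, and no biological explanation was tested.

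Summit positions fell on a grid. Of the 7709 summits, 5955 (77.2%) were exact multiples of 32 bp, where an even spread would give 3.13%. A candidate explanation is that summits were read from a signal stored in 32 bp bins, with tied bins averaged, which predicts that remainders fall on 0 or on the mean of 2 to 4 tied bins. These remainders held 99.86% of summits but 22.18% of interval starts, against 21.9% for an even spread. If so, the summits locate the EGR1 ChIP signal to about a bin, and motif distances finer than 32 bp could not be read from them.

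The smallest gap between adjacent intervals was 76 bp and the smallest width was 207 bp. Whether the peak caller set these limits is unknown, because its options are not given in the sources used here.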
